A study of Mus musculus with 12 samples.

How the data were processed

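HSPCs came from C57BL/6 mice of 4 genotype groups, 3 libraries each. Per the labels, mice aged 4 to 6 weeks were given 7 intraperitoneal doses of pIpC (1 mg/mL), 1 every other day, and cells were taken 4 to 6 weeks later by red cell lysis and lineage depletion. Per the labels' protocols, total RNA was extracted with Trizol and poly(A) libraries were made with the NEBNext Ultra II RNA kit, a version that keeps no record of strand. The labels do not say whether the 3 libraries of a group came from separate mice, and they give no sex, allele or Cre driver.

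Reads were aligned with STAR to mouse genome build mm9 and compared with DESeq2 by the authors, per the submitters' processing notes, and tool versions and the read counter are not given in the sources used here. The authors deposited 3 comparisons with WT, each with 33018 RefSeq transcripts, and per the file headers each holds a mean of normalized counts, made by dividing counts by library size factors. The log2 fold changes and their standard errors were computed by the authors with DESeq2, per the file headers, and lie near 0, as moderated estimates do, for transcripts with few reads and for some with many reads, such as Xist. The score of each transcript is the Wald statistic deposited by the authors, the fold change divided by its standard error. The p-values are those of the authors' Wald test, and the adjusted p-values, per the file headers, leave out transcripts with low means. Means of the same transcript differ between the deposited tables, so each comparison was normalized by itself. The tables hold no values per library, so every value rests on the authors' fit.

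For each gene symbol the transcript with the highest mean over the 3 comparisons was kept, which gave 24016 genes, and 4911 genes had several transcripts. The 53 symbols that a spreadsheet had turned into dates were matched by accession. A gene was counted as changed at an authors' adjusted p under 0.05. Differences between genotype groups (Double minus Npm1, Double minus Smc3, and Double minus the sum of both) were tested with a normal z test whose variance is the sum of the squared standard errors, then Benjamini-Hochberg adjusted. Gene lists were tested with cameraPR of limma 3.58.1 on the Wald statistic (for differences, on z) with an inter-gene correlation of 0.01, adjusted over the lists of a comparison. A correlation could not be estimated without values per library. Library size factors were read from transcripts with a mean under 0.6, whose values are whole reads divided by a library's size factor. Depth was each size factor times the summed means of the kept transcripts. All of 3259, 3078 and 3428 such transcripts in the Smc3, Npm1 and Double comparisons fitted whole reads at a relative tolerance of 1e-09, and 0% of shifted values did. The median standard error of genes with a mean of at least 50 was 0.129, 0.124 and 0.133 on the log2 scale. GC content came from GENCODE M21 transcripts on GRCm38 for 97.7% of genes, so no coordinates are given.

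Gene lists, the rule for named genes, tests and alternatives were fixed before the data were examined, except GC removal, the 2 other choices of transcript and leaving genes without a p out of differences, which came after. The tests of explanations in the closing sections, save that of depth, also came after. Genes named are Smc3, Npm1, Dock1 and Rac2, the 10 most positive and 10 most negative changes with adjusted p under 0.05 and a mean of at least 50 in each comparison, up to 4 members of each list with the smallest p, and Hoxa9, Hoxa10, Meis1 and Cdkn1a, without receptor segments and genes named Gm with digits or ending in Rik. For differences they are the 5 most positive and 5 most negative past the threshold, and other genes are said to be chosen after their values were seen. The 25 lists with members in the tables were cohesin, HoxA, HoxB, Hox cofactors, Hox chromatin regulators, DOCK, ELMO and RAC signalling, stem cell, neutrophil, monocyte, erythroid, megakaryocyte, B cell, plasma cell, T and NK cell, basophil, stromal, interferon, NF-kappaB, S phase, G2 and M phase, p53, ribosome biogenesis, MAPK feedback, immediate early and sex-linked genes. Mitochondrially encoded genes were absent from the tables. Genes such as Flt3, Gata2, Hoxb5, Mecom and Mllt3 stand in 2 lists each.

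The methods were tested on simulated data. For the statistics of Double against WT (19567 genes), cameraPR recovered 98.7% of 300 shifted lists and called 0.471% of 850 unshifted lists. The simulated genes were drawn as independent, so this false rate does not cover correlation between members of real lists. The z test, run on 18199 simulated genes with 200 changed, recovered 84.3% of changes of 1 on the log2 scale for Double against Npm1, 84.8% for Double against Smc3 and 71.7% for Double against the sum. Of its calls 0.217%, 0.182% and 0.703% were false. With the WT share of the variance removed, recovery was 95.4%, 94.9% and 81.7%, and 5.08%, 5.06% and 4.99% of calls were false. The simulated changes were set only in genes with a mean of at least 50 and were not moderated towards 0. Recovery in the real data may therefore be lower. Alternatives were other thresholds and adjustments, filters on the mean, a median fold change set to 0, the WT share removed, a correlation of 0.05 and ranks for lists, and removal of the GC trend by subtracting the median over bins of GC content. Unstranded libraries cannot separate overlapping genes, and near-identical genes share reads. The 37, 15 and 48 transcripts with a fold change but no p were left out of the comparisons with WT. Differences used their fold changes and standard errors, and leaving them out there was an alternative. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3 were used.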

Results

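RNA-seq was read from lineage-depleted hematopoietic stem and progenitor cells (HSPCs) of C57BL/6 mice, in 12 libraries that the labels place in 4 genotype groups of 3 named WT, Smc3, Npm1 and Double. Smc3 is a subunit of cohesin, the ring complex that holds sister chromatids together and shapes chromatin loops, and Npm1 is a nucleolar chaperone that is often mutated in acute myeloid leukaemia (AML). The series title places DOCK1 and RAC2, an activator of Rac GTPases and a Rac GTPase of blood cells, at the centre of AML with both lesions. The labels name no allele, and all mice received pIpC, a double-stranded RNA mimic often used to switch on Cre. The authors deposited 3 tables, each comparing 1 genotype group with WT, with no values per library, so each value below carries the standard error of the authors' fit and no spread between libraries. Library size factors were read from transcripts with about 1 read, and depth is each factor times the summed means of the kept transcripts. It was about 10.24 to 22.03 M reads per WT library over the 3 tables, 19.8 to 51.6 M for Smc3, 10.6 to 33.1 M for Npm1 and 27.8 to 35.4 M for Double.

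The first comparison asked how Smc3 HSPCs differed from WT. Smc3 held libraries of male mice and WT did not, as given below, and its mean library size factor was 2.15 times that of WT. Sex and depth therefore differ along with genotype. The basophil, mast cell and eosinophil list was higher in Smc3 HSPCs, as were, with fewer of their members called, the monocyte list and the DOCK, ELMO and RAC list, while the erythroid, S phase and ribosome biogenesis lists were lower. Carboxypeptidase A3 (Cpa3), a mast cell and basophil protease, rose by a log2 fold change of 1.33 ± 0.17 (standard error, 3 against 3 libraries, adjusted p = 1.84e-10) in the authors' deposited table. The red cell anion exchanger Slc4a1 fell, at -0.997 ± 0.146 (adjusted p = 9.77e-09) in the authors' deposited table. In all, 1854 genes changed of 12750 with an adjusted p, 1012 higher and 842 lower, and 41 of the higher and 8 of the lower reached a log2 fold change of 1 in size in the authors' deposited table.

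The Smc3 transcript itself stood at -0.02 ± 0.11 (p = 0.868) in the authors' deposited table, so no fall of the targeted gene was seen. A value over the whole transcript may miss a deletion of part of the gene. As the labels name no allele, whether a fall should show is not known, and the value checks no label. Npm1 stood at -0.26 ± 0.11 (adjusted p = 0.0805) and Dock1 at 0.36 ± 0.20 (adjusted p = 0.222), neither past the threshold, while Rac2 rose by 0.38 ± 0.14 (adjusted p = 0.0397) in the authors' deposited table. Adjusted over Smc3, Npm1, Dock1 and Rac2 alone, p was 0.0309 for Npm1 and 0.0204 for Rac2 here, 0.00599 for Dock1 and 1.21e-05 for Rac2 in Npm1, and 0.0277 for Dock1 in Double. The largest rises in the authors' deposited table were Alox15 at 1.38 ± 0.22, the synaptic scaffold gene Pdzd4 at 1.37 ± 0.21, the basophil receptor Cd200r3 at 1.36 ± 0.23, the lectin-like gene Clec2i at 1.35 ± 0.19 and the potassium channel Kcnj2 at 1.34 ± 0.19. After Cpa3 came Cd200r1 at 1.22 ± 0.21, the nucleotide receptor P2ry14 at 1.22 ± 0.20, the adhesion molecule L1cam at 1.16 ± 0.20 and the interleukin 18 receptor chain Il18rap at 1.16 ± 0.21 in the authors' deposited table. The deepest falls in the authors' deposited table were Id3, an inhibitor of helix-loop-helix factors, at -1.48 ± 0.24, the antiviral enzyme Rsad2 at -1.20 ± 0.16, the inhibitory Smad gene Smad7 at -1.11 ± 0.18, Sowaha at -1.10 ± 0.15 and the phosphatase Ptpn13 at -1.09 ± 0.19. Slc4a1, the interferon-induced Isg15 at -0.99 ± 0.20 and Oasl1 at -0.95 ± 0.17, Il1b at -0.94 ± 0.25 and Prelid2 at -0.92 ± 0.15 completed the list of 10 in the authors' deposited table.

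Of the basophil, mast cell and eosinophil genes, 11 of 11 measured members rose (11 adjusted over the list alone) in the authors' deposited table, with Hdc, the histamine-forming enzyme, at 0.93 ± 0.17 and the high-affinity IgE receptor Fcer1a at 0.98 ± 0.20. cameraPR on the basophil, mast cell and eosinophil genes gave adjusted p = 1.1e-18. The list has 3 more members, Prg2, Ear1 and Ear2, that carry no p and stood at 0.60 to 0.92 in the authors' deposited table. Of the neutrophil and granule genes, 5 of 13 measured members rose (8 adjusted over the list alone) in the authors' deposited table, among them the granule protease Ctsg at 0.80 ± 0.16 and Mpo at 0.70 ± 0.17. cameraPR on the neutrophil and granule genes gave adjusted p = 1.73e-05. The other 7 listed neutrophil genes, Camp, Ltf and Mmp9 among them, carry no p and stood at -0.57 to -0.38 in the authors' deposited table, so the list test covers only part of the list. In the authors' DESeq2 fit a fold change without a p marks a gene for which a library lies far from the rest, and the tables do not show which library. Camp, Ltf, Mmp8, Mmp9, Ngp and Retnlg lack a p in all 3 tables, which share the WT libraries, so a WT library apart from the others in these genes is not excluded and bears on every neutrophil list result. Of the monocyte, macrophage and dendritic cell genes, 7 of 28 measured members rose (9 adjusted over the list alone) in the authors' deposited table, with Siglech at 0.95 ± 0.25, Ccr2 at 0.81 ± 0.19 and the cytokine receptor Flt3 at 0.58 ± 0.15. cameraPR on the monocyte, macrophage and dendritic cell genes gave adjusted p = 1.73e-05. Of the DOCK, ELMO and RAC genes, 9 of 26 measured members rose (9 adjusted over the list alone) in the authors' deposited table, led by Arhgap15 at 0.67 ± 0.16, Elmo1 at 0.57 ± 0.17 and Arhgdib at 0.55 ± 0.17. cameraPR on the DOCK, ELMO and RAC genes gave adjusted p = 1.74e-05.

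Of the erythroid genes, 13 of 21 measured members fell (18 adjusted over the list alone) in the authors' deposited table, and the haemoglobin genes Hba-a1 and Hbb-b1 stood at -0.84 ± 0.17 and -0.75 ± 0.20, although near-identical globin copies share reads. cameraPR on the erythroid genes gave adjusted p = 2.06e-15. Of the ribosome biogenesis genes, 12 of 25 measured members fell (18 adjusted over the list alone) in the authors' deposited table, with nucleolin (Ncl) at -0.34 ± 0.09 and Ddx21 at -0.37 ± 0.10. cameraPR on the ribosome biogenesis genes gave adjusted p = 6.53e-13. Of the S phase genes, 10 of 25 measured members fell (15 adjusted over the list alone) in the authors' deposited table, with Mcm5 of the replicative helicase at -0.31 ± 0.08 and the licensing factor Cdt1 at -0.37 ± 0.10. cameraPR on the S phase genes gave adjusted p = 1.59e-11. Of the immediate early genes, 4 of 19 measured members fell (5 adjusted over the list alone) in the authors' deposited table, with Fosb at -0.84 ± 0.24. cameraPR on the immediate early genes gave adjusted p = 6.74e-06. The megakaryocyte list was higher with 5 of 15 members called, the integrin Itgb3 at 0.82 ± 0.12 in the authors' deposited table (cameraPR adjusted p = 0.00321, 5 rose and 1 fell adjusted over the list alone). Type I interferon genes were lower as a list, where 1 rose and 5 fell of 30 in the authors' deposited table and 1 and 6 did so adjusted over the list alone (cameraPR adjusted p = 0.00589, 0.0623 at an inter-gene correlation of 0.05, 0.00177 to 0.0623 over 4 alternative settings). The stromal and endothelial list was higher (cameraPR adjusted p = 0.00589, 0.000835 to 0.0789 over the alternatives), yet 1 of 16 members passed the test over all genes and 1 adjusted over the list alone, the pericyte receptor Pdgfrb at 0.78 ± 0.16 in the authors' deposited table. The T and NK cell list was higher with 4 of 19 members called (4 adjusted over the list alone), the NK receptor Ncr1 at 0.86 ± 0.22 in the authors' deposited table (cameraPR adjusted p = 0.0248, 0.103 at a correlation of 0.05, 0.015 to 0.103 over the alternatives). The G2 and M phase list was lower with 2 of 26 called (0 adjusted over the list alone), Plk1 and Cenpa at -0.29 and -0.29 in the authors' deposited table (cameraPR adjusted p = 0.0248, 0.123 at a correlation of 0.05, 0.00564 to 0.149 over the alternatives).

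In Smc3 against WT 12 lists were not called. Of 10 HoxA genes, 0 rose and 0 fell in the authors' deposited table, and 0 and 0 adjusted over the list alone (cameraPR adjusted p = 0.339). Of 9 HoxB genes, 0 rose and 1 fell in the authors' deposited table, and 0 and 1 adjusted over the list alone (cameraPR adjusted p = 0.866). Of 12 Hox cofactor genes, 1 rose and 0 fell in the authors' deposited table, and 1 and 0 adjusted over the list alone (cameraPR adjusted p = 0.2). Of 14 Hox chromatin regulator genes, 0 rose and 1 fell in the authors' deposited table, and 0 and 1 adjusted over the list alone (cameraPR adjusted p = 0.101). Of 15 cohesin genes, 0 rose and 0 fell in the authors' deposited table, and 0 and 0 adjusted over the list alone (cameraPR adjusted p = 0.145). Of 20 stem cell genes, 5 rose and 1 fell in the authors' deposited table, and 5 and 2 adjusted over the list alone (cameraPR adjusted p = 0.145).

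The other lists not called in Smc3 held signalling, lymphoid and sex-linked genes. Of 18 B cell genes, 1 rose and 1 fell in the authors' deposited table, and 1 and 1 adjusted over the list alone (cameraPR adjusted p = 0.76). Of 8 plasma cell genes, 0 rose and 0 fell in the authors' deposited table, and 0 and 0 adjusted over the list alone (cameraPR adjusted p = 0.475). Of 22 NF-kappaB genes, 1 rose and 2 fell in the authors' deposited table, and 2 and 2 adjusted over the list alone (cameraPR adjusted p = 0.866). Of 21 p53 target genes, 0 rose and 1 fell in the authors' deposited table, and 0 and 1 adjusted over the list alone (cameraPR adjusted p = 0.687). Of 14 MAPK feedback genes, 1 rose and 2 fell in the authors' deposited table, and 1 and 2 adjusted over the list alone (cameraPR adjusted p = 0.339). Of 6 sex-linked genes, 0 rose and 0 fell in the authors' deposited table, and 0 and 0 adjusted over the list alone (cameraPR adjusted p = 0.687). Hoxa9 stood at 0.31 ± 0.16 and Hoxa10 at 0.11 ± 0.25 in the authors' deposited table, with adjusted p = 0.188 and 0.806. The pro-apoptotic p53 target Bbc3 fell to -0.85 ± 0.13 (adjusted p = 1.1e-07) and the stem cell antigen Cd34 rose by 0.62 ± 0.15 (adjusted p = 0.00199) in the authors' deposited table. For HoxB, NF-kappaB and B cell genes the median (0.03, 0.01, -0.02) and the mean (-0.02, -0.02, 0.03) differ in sign, with the test on the side of the mean. At an inter-gene correlation of 0.05 cameraPR still called every list named above as called except interferon, T and NK cell and G2 and M phase genes. Of the lists not called, the cohesin list was called as lower with the GC trend removed (adjusted p = 0.0316, 0.0316 to 0.358 over the alternatives). The Smc3 and WT libraries together held a summed mean of 2022 normalized counts of 4 Y-linked genes, against 3.80 in the Npm1 and WT libraries, and Xist in Smc3 lay at 33.5% of its WT level, so Smc3 held libraries of male mice and WT did not. The sex-linked list cannot show this, because the moderated fold change of Xist was -0.06 ± 0.10 in the authors' deposited table. Setting the median fold change to 0 moved the split of calls from 54.6% higher to 63.1%, and removing the trend with transcript GC content moved it to 66.1%.

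**Figure D1:**
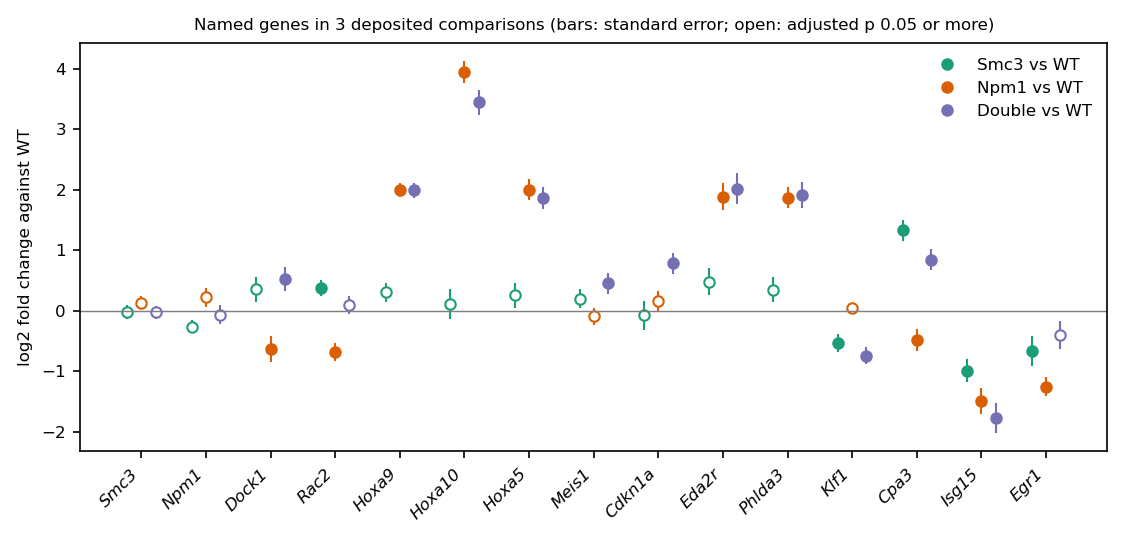
Log2 fold change against WT (vertical axis) of 15 named genes (horizontal axis) in the authors' 3 deposited comparisons, each of 3 against 3 libraries. Points are fold changes, bars their standard errors, and filled points have an adjusted p under 0.05, as Hoxa10 does in Npm1 at 3.94 and in Double at 3.45.

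The second comparison asked what the Npm1 genotype did on its own. The HoxA and p53 target lists were higher in Npm1 HSPCs, and the interferon, immediate early, NF-kappaB and DOCK, ELMO and RAC lists were lower. Hoxa10, a homeobox gene of early progenitors, rose by 3.94 ± 0.19 on the log2 scale, a 15.4-fold rise (adjusted p = 1.98e-96), and Hoxa9 rose by 2.00 ± 0.12 (adjusted p = 1.11e-59) in the authors' deposited table. Rac2 fell, at -0.68 ± 0.15 (adjusted p = 0.000183), and so did Dock1, at -0.63 ± 0.21 (adjusted p = 0.0251), in the authors' deposited table. In all, 2230 genes changed of 12324 with an adjusted p, 1121 higher and 1109 lower, of which 33 and 41 reached a log2 fold change of 1 in size in the authors' deposited table.

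The Npm1 transcript stood at 0.22 ± 0.16 (adjusted p = 0.323) and Smc3 at 0.14 ± 0.11 (adjusted p = 0.39) in the authors' deposited table, and a mutation that leaves the transcript level as it is would not show here. After Hoxa10 the largest rises in the authors' deposited table were the glycosyltransferase gene Mgat4c at 3.00 ± 0.22, Hoxa5 at 2.00 ± 0.18, Hoxa9, the homeodomain-only protein Hopx at 1.90 ± 0.21 and the p53-induced receptor Eda2r at 1.89 ± 0.23. The p53 targets Phlda3 at 1.87 ± 0.17 and Zmat3 at 1.70 ± 0.16, the folate receptor Folr1 at 1.74 ± 0.24 and the Wnt inhibitor Sfrp4 at 1.59 ± 0.22 followed in the authors' deposited table. The deepest falls in the authors' deposited table were Tinagl1 at -2.44 ± 0.21, the interferon-induced membrane protein Ifitm1 at -1.90 ± 0.17, Isg15 at -1.49 ± 0.22, Ppp1r9a at -1.32 ± 0.18 and the metalloproteinase inhibitor Timp2 at -1.28 ± 0.19. The immediate early factor Egr1 at -1.25 ± 0.15, Rgs9bp at -1.25 ± 0.20, Ndrg2 at -1.21 ± 0.21, Tmcc2 at -1.21 ± 0.16 and the histone gene H2afj at -1.20 ± 0.13 completed the list in the authors' deposited table.

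Of the HoxA genes, 8 of 10 measured members rose (9 adjusted over the list alone) in the authors' deposited table, Hoxa7 among them at 1.45 ± 0.15 (cameraPR adjusted p = 9.11e-51), and overlapping or antisense transcripts of the cluster share reads that a library without strand cannot assign. Of the p53 targets, 7 rose and 0 fell of 23 measured (10 and 2 adjusted over the list alone) in the authors' deposited table, with Ccng1 at 1.26 ± 0.15 (cameraPR adjusted p = 2.62e-09), while the cell cycle inhibitor Cdkn1a stood at 0.17 ± 0.16 (adjusted p = 0.479) in the authors' deposited table. Of the type I interferon genes, 18 of 30 measured members fell (20 adjusted over the list alone) in the authors' deposited table, with the antiviral oligoadenylate synthetase genes Oas2 at -1.34 ± 0.22 and Oasl2 at -1.16 ± 0.20 and the nucleic acid sensor Zbp1 at -1.01 ± 0.23. cameraPR on the type I interferon genes gave adjusted p = 6.55e-15. The interferon list was also lower than WT in the other groups, at medians of -0.15 in Smc3 and -0.41 in Double beside -0.60 here. WT libraries apart from the rest would lower it in all 3 comparisons, which was not tested for this list. Double against Smc3, where WT is taken out, had a median difference of -0.34 in it. Of the immediate early and dissociation genes, 13 of 20 measured members fell (16 adjusted over the list alone) in the authors' deposited table, with Junb at -0.89 ± 0.12 and Jun at -0.88 ± 0.16. cameraPR on the immediate early and dissociation genes gave adjusted p = 1.35e-15. Of the NF-kappaB genes, 8 of 22 measured members fell (10 adjusted over the list alone) in the authors' deposited table, led by the inhibitor Nfkbia at -0.56 ± 0.12 and the chemokine Cxcl2 at -0.93 ± 0.21. cameraPR on the NF-kappaB genes gave adjusted p = 4.22e-06. Of the MAPK feedback genes, 5 of 14 measured members fell (5 adjusted over the list alone) in the authors' deposited table, with the phosphatase Dusp5 at -0.87 ± 0.21. cameraPR on the MAPK feedback genes gave adjusted p = 0.000228.

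Of the DOCK, ELMO and RAC genes, 11 fell and 1 rose of 26 measured (12 and 2 adjusted over the list alone) in the authors' deposited table, and Vav1, Dock8 and Arhgdib stood at -0.46 ± 0.12, -0.34 ± 0.08 and -0.56 ± 0.12. cameraPR on the DOCK, ELMO and RAC genes gave adjusted p = 5.84e-05. Of the neutrophil and granule genes, 3 of 11 measured members fell (7 adjusted over the list alone) in the authors' deposited table, Ms4a3 of granulocyte and monocyte progenitors at -0.80 ± 0.21 and the growth factor receptor Csf3r at -0.70 ± 0.21. cameraPR on the neutrophil and granule genes gave adjusted p = 2.74e-05. The 9 neutrophil genes without a p stood at -0.52 to -0.31 in the authors' deposited table, the same direction as the tested part. Of the basophil, mast cell and eosinophil genes, 6 of 13 measured members fell (7 adjusted over the list alone) in the authors' deposited table, with the basophil protease Mcpt8 at -0.87 ± 0.19. cameraPR on the basophil, mast cell and eosinophil genes gave adjusted p = 0.0005. The monocyte, macrophage and dendritic cell list was lower at a median log2 fold change of -0.34 (cameraPR adjusted p = 0.000492), though 1 of 28 members, Itgam at -0.65 ± 0.21, passed over all genes and 0 adjusted over the list alone in the authors' deposited table. Of the ribosome biogenesis genes, 5 rose and 0 fell of 25 measured (8 and 1 adjusted over the list alone) in the authors' deposited table, with Utp20 at 0.46 ± 0.15. cameraPR on the ribosome biogenesis genes gave adjusted p = 0.000126. Of the cohesin genes, 4 of 15 measured members rose (4 adjusted over the list alone) in the authors' deposited table, the release factor Wapl (listed as Wapal) at 0.40 ± 0.10, the loader Nipbl at 0.32 ± 0.10 and the acetyltransferases Esco2 at 0.53 ± 0.17 and Esco1 at 0.39 ± 0.13. cameraPR on the cohesin genes gave adjusted p = 0.000554, 0.00033 to 0.267 over the alternatives, the highest with the GC trend removed. Of the S phase genes, 5 of 25 measured members rose (5 adjusted over the list alone), Ccne1 at 0.34 ± 0.08 in the authors' deposited table. cameraPR on the S phase genes gave adjusted p = 0.041, 0.15 at a correlation of 0.05, 0.0398 to 0.207 over the alternatives. Of the G2 and M phase genes, 1 of 26 measured members rose (0 adjusted over the list alone), Bub1 at 0.32 ± 0.11 in the authors' deposited table. cameraPR on the G2 and M phase genes gave adjusted p = 0.041, 0.15 at a correlation of 0.05, 0.00619 to 0.82 over the alternatives. Of the HoxB genes, 2 of 9 measured members rose (2 adjusted over the list alone), Hoxb5 at 1.30 ± 0.24 in the authors' deposited table. cameraPR on the HoxB genes gave adjusted p = 0.0457, 0.101 at a correlation of 0.05, 0.00325 to 0.211 over the alternatives.

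In Npm1 against WT 10 lists were not called. Of 21 erythroid genes, 4 rose and 4 fell in the authors' deposited table, and 5 and 6 adjusted over the list alone (cameraPR adjusted p = 0.651). Of 15 megakaryocyte genes, 2 rose and 2 fell in the authors' deposited table, and 2 and 2 adjusted over the list alone (cameraPR adjusted p = 0.899). Of 20 stem cell genes, 2 rose and 2 fell in the authors' deposited table, and 3 and 2 adjusted over the list alone (cameraPR adjusted p = 0.685). Of 12 Hox cofactor genes, 0 rose and 2 fell in the authors' deposited table, and 0 and 2 adjusted over the list alone (cameraPR adjusted p = 0.698). Of 14 Hox chromatin regulator genes, 0 rose and 1 fell in the authors' deposited table, and 0 and 0 adjusted over the list alone (cameraPR adjusted p = 0.469). Of 17 B cell genes, 0 rose and 0 fell in the authors' deposited table, and 0 and 0 adjusted over the list alone (cameraPR adjusted p = 0.0696). Of 8 plasma cell genes, 0 rose and 0 fell in the authors' deposited table, and 0 and 0 adjusted over the list alone (cameraPR adjusted p = 0.235). Of 19 T and NK cell genes, 0 rose and 2 fell in the authors' deposited table, and 0 and 2 adjusted over the list alone (cameraPR adjusted p = 0.0586). Of 16 stromal genes, 0 rose and 0 fell in the authors' deposited table, and 0 and 0 adjusted over the list alone (cameraPR adjusted p = 0.283). Of 6 sex-linked genes, 0 rose and 0 fell in the authors' deposited table, and 0 and 0 adjusted over the list alone (cameraPR adjusted p = 0.781).

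At an inter-gene correlation of 0.05 cameraPR kept its call on all but the HoxB, S phase and G2 and M phase lists. On ranks the B cell and T and NK cell lists were called too, as lower (adjusted p = 0.0113 and 0.0175, 0.0113 to 0.191 and 0.0175 to 0.179 over the alternatives), and so, against its direction before, was the sex-linked list with the GC trend removed (0.0165, 0.0165 to 0.942). The erythroid genes went both ways, Car1 rising by 0.61 ± 0.14 (adjusted p = 0.000604) and the haem synthesis gene Alas2 falling to -0.72 ± 0.17 (adjusted p = 0.00069) in the authors' deposited table, and their median of -0.06 and mean of -0.03 differ in sign from the test's upward direction. The megakaryocyte genes had a median just below 0, with the mean (0.02) and the test above it. Meis1, a Hox cofactor, stood at -0.09 ± 0.14 (adjusted p = 0.666) in the authors' deposited table. The fold changes fell with the GC content of the transcript (Spearman's correlation = -0.44 across 10944 genes, which are not independent), from a median of 0.21 in the lowest of 10 GC bins to -0.19 in the highest. With that trend removed 1385 genes were called, 405 higher and 980 lower, and with the median set to 0 the split of calls moved from 50.3% higher to 37.7%.

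**Figure D2:**
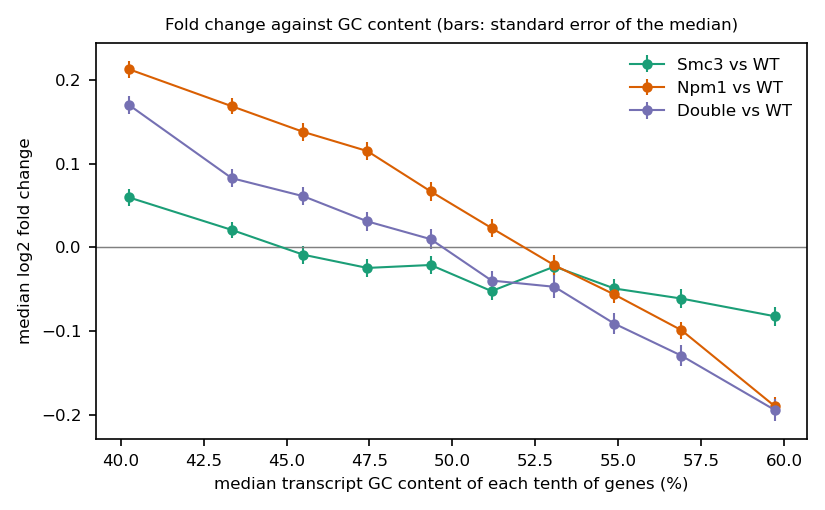
Median log2 fold change against WT (vertical axis) in 10 bins of 10944 genes ordered by transcript GC content (horizontal axis, percent) in the 3 deposited comparisons. Bars are standard errors of the median, and the line for Npm1 falls from 0.21 to -0.19.

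The third comparison asked how Double HSPCs differed from WT. Here too male libraries sat in Double and not in WT, and the mean library size factor was 2.1 times that of WT. Sex and depth again differ along with genotype. In Double HSPCs the HoxA list, the p53 target list and the basophil, mast cell and eosinophil list were higher, and the erythroid, S phase and interferon lists were lower. Hoxa10 rose by 3.45 ± 0.20, a 10.9-fold rise (adjusted p = 7.82e-60), and the matricellular gene Spon2 fell to -3.04 ± 0.20 (adjusted p = 4.19e-51) in the authors' deposited table. Dock1 rose by 0.53 ± 0.19 (adjusted p = 0.0403) and Rac2 stood at 0.10 ± 0.15 (adjusted p = 0.71) in the authors' deposited table. In all, 2470 genes changed of 13217 with an adjusted p, 1172 higher and 1298 lower, of which 61 and 95 reached a log2 fold change of 1 in size in the authors' deposited table.

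The Smc3 transcript stood at -0.03 ± 0.11 (adjusted p = 0.917) and Npm1 at -0.06 ± 0.16 (adjusted p = 0.853) in the authors' deposited table. Behind Hoxa10 the largest rises in the authors' deposited table were the nuclear receptor Hnf4a at 2.16 ± 0.22, Eda2r at 2.02 ± 0.26, Mgat4c at 2.00 ± 0.26, Hoxa9 at 1.99 ± 0.12 and Phlda3 at 1.92 ± 0.22. Hoxa5 at 1.87 ± 0.18, Hoxa3 at 1.70 ± 0.22, Hopx at 1.67 ± 0.23 and the RNA Mira at 1.58 ± 0.17 followed in the authors' deposited table. Behind Spon2 the deepest falls in the authors' deposited table were Tinagl1 at -2.58 ± 0.22, the sulfate transporter Slc26a1 at -2.21 ± 0.19, endosialin (Cd248) at -2.12 ± 0.24, Rsad2 at -1.91 ± 0.14 and Tmem246 at -1.91 ± 0.22. The epoxide hydrolase Ephx2 at -1.86 ± 0.20, a gene whose name the file shows as a date and whose accession gives Septin4 at -1.83 ± 0.19, Prss50 at -1.80 ± 0.19 and the phosphatase Ptpn14 at -1.79 ± 0.19 completed the list in the authors' deposited table. Meis1 rose by 0.46 ± 0.17 (adjusted p = 0.0471) and Cdkn1a by 0.79 ± 0.17 (adjusted p = 0.000138) in the authors' deposited table.

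Of the HoxA genes, 7 of 10 measured members rose (9 adjusted over the list alone) in the authors' deposited table, Hoxa7 at 1.52 ± 0.16. cameraPR on the HoxA genes gave adjusted p = 1.62e-37. Of the p53 targets, 11 rose and 1 fell of 23 measured (11 and 1 adjusted over the list alone) in the authors' deposited table, Zmat3 at 1.41 ± 0.21 and Ccng1 at 0.95 ± 0.16. cameraPR on the p53 targets gave adjusted p = 2.48e-09. Of the basophil, mast cell and eosinophil genes, 8 of 14 measured members rose (9 adjusted over the list alone) in the authors' deposited table, with the eosinophil granule genes Prg2 at 1.18 ± 0.26 and Prg3 at 1.16 ± 0.26 and the interleukin 5 receptor Il5ra at 1.13 ± 0.26. cameraPR on the basophil, mast cell and eosinophil genes gave adjusted p = 4.38e-08. Among the other members, Mcpt8, Hdc, Fcer1a and Cd200r3 did not pass in Double, at 0.22, 0.51, -0.01 and 0.21 in the authors' deposited table (chosen after their values were seen). Of the neutrophil and granule genes, 6 of 11 measured members rose (6 adjusted over the list alone) in the authors' deposited table, neutrophil elastase (Elane) at 0.81 ± 0.16. cameraPR on the neutrophil and granule genes gave adjusted p = 3.89e-05. The 9 neutrophil genes without a p, Camp, Ltf and Mmp9 among them, stood at -0.68 to -0.50 in the authors' deposited table, against the direction of the tested part. Of the monocyte, macrophage and dendritic cell genes, 8 rose and 2 fell of 28 measured (8 and 2 adjusted over the list alone) in the authors' deposited table, with the transglutaminase F13a1 at 1.04 ± 0.14 and Ccr2 at 0.75 ± 0.14. cameraPR on the monocyte, macrophage and dendritic cell genes gave adjusted p = 0.00187. Of the DOCK, ELMO and RAC genes, 5 of 26 measured members rose (6 adjusted over the list alone) in the authors' deposited table, the guanine nucleotide exchange factor Vav3 at 0.69 ± 0.17, Arhgap15 at 0.66 ± 0.16 and Elmo1 at 0.62 ± 0.15. cameraPR on the DOCK, ELMO and RAC genes gave adjusted p = 0.000101.

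Of the erythroid genes, 16 of 21 measured members fell (16 adjusted over the list alone) in the authors' deposited table, with Alas2 at -1.29 ± 0.17, Hba-a1 at -1.20 ± 0.17 and the blood group gene Rhd at -1.03 ± 0.17. cameraPR on the erythroid genes gave adjusted p = 2.58e-19. Of the type I interferon genes, 1 rose and 12 fell of 30 measured (1 and 14 adjusted over the list alone) in the authors' deposited table, with Isg15 at -1.77 ± 0.25, Oas3 at -1.37 ± 0.22 and Irf7 at -1.33 ± 0.22. cameraPR on the type I interferon genes gave adjusted p = 2.6e-10. Of the S phase genes, 10 of 25 measured members fell (13 adjusted over the list alone) in the authors' deposited table, Cdt1 at -0.54 ± 0.10 and Mcm7 at -0.40 ± 0.10. cameraPR on the S phase genes gave adjusted p = 8.72e-08. Of the G2 and M phase genes, 3 of 26 measured members fell (3 adjusted over the list alone) in the authors' deposited table, Cenpa at -0.42 ± 0.09. cameraPR on the G2 and M phase genes gave adjusted p = 0.0014. Of the HoxB genes, 3 of 9 measured members rose (3 adjusted over the list alone) in the authors' deposited table, Hoxb4 at 0.79 ± 0.18. cameraPR on the HoxB genes gave adjusted p = 0.0267, 0.0662 at a correlation of 0.05, 0.00272 to 0.09 over the alternatives. Of the Hox cofactor list, 3 of 12 measured members rose (5 adjusted over the list alone) in the authors' deposited table, Nkx2-3 at 1.00 ± 0.26. cameraPR on the Hox cofactor list gave adjusted p = 0.0479, 0.109 at a correlation of 0.05, 0.0592 to 0.196 over the alternatives. Of the T and NK cell genes, 2 of 19 measured members rose (2 adjusted over the list alone) in the authors' deposited table, Nkg7 at 0.64 ± 0.14. cameraPR on the T and NK cell genes gave adjusted p = 0.0267, 0.101 at a correlation of 0.05, 0.0113 to 0.101 over the alternatives. The immediate early list was lower with 0 of 20 members called over all genes and 0 adjusted over the list alone, Egr1 standing at -0.40 ± 0.24 in the authors' deposited table (Egr1 chosen after its value was seen, cameraPR adjusted p = 0.0211, 0.0877 at a correlation of 0.05, 0.00054 to 0.155 over the alternatives).

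In Double against WT 11 lists were not called. Of 20 stem cell genes, 3 rose and 2 fell in the authors' deposited table, and 4 and 2 adjusted over the list alone (cameraPR adjusted p = 0.578). Of 15 megakaryocyte genes, 1 rose and 1 fell in the authors' deposited table, and 2 and 1 adjusted over the list alone (cameraPR adjusted p = 0.322). Of 17 B cell genes, 0 rose and 2 fell in the authors' deposited table, and 0 and 1 adjusted over the list alone (cameraPR adjusted p = 0.0943). Of 8 plasma cell genes, 0 rose and 0 fell in the authors' deposited table, and 0 and 0 adjusted over the list alone (cameraPR adjusted p = 0.876). Of 15 cohesin genes, 0 rose and 0 fell in the authors' deposited table, and 0 and 0 adjusted over the list alone (cameraPR adjusted p = 0.773). Of 14 Hox chromatin regulator genes, 0 rose and 3 fell in the authors' deposited table, and 0 and 3 adjusted over the list alone (cameraPR adjusted p = 0.0723).

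The other lists not called in Double held signalling, stromal and sex-linked genes. Of 25 ribosome biogenesis genes, 0 rose and 1 fell in the authors' deposited table, and 0 and 0 adjusted over the list alone (cameraPR adjusted p = 0.0526). Of 22 NF-kappaB genes, 1 rose and 2 fell in the authors' deposited table, and 1 and 2 adjusted over the list alone (cameraPR adjusted p = 0.422). Of 14 MAPK feedback genes, 1 rose and 2 fell in the authors' deposited table, and 1 and 2 adjusted over the list alone (cameraPR adjusted p = 0.288). Of 16 stromal genes, 1 rose and 0 fell in the authors' deposited table, and 1 and 0 adjusted over the list alone (cameraPR adjusted p = 0.0723). Of 6 sex-linked genes, 0 rose and 0 fell in the authors' deposited table, and 0 and 0 adjusted over the list alone (cameraPR adjusted p = 0.709). With the inter-gene correlation at 0.05, only the HoxB, Hox cofactor, T and NK cell and immediate early lists of Double lost their call. On ranks the B cell and ribosome biogenesis lists were called too, as lower, and the stromal list as higher (adjusted p = 0.0356, 0.00278 and 0.0356, with 0.0356 to 0.307, 0.00278 to 0.196 and 0.0356 to 0.196 over the alternatives). Y-linked genes summed to a mean of 2280 normalized counts in the Double and WT libraries, and Xist in Double lay at 40.7% of its WT level. Fold changes fell with GC content here too (Spearman's correlation = -0.36), and with the trend removed 1842 genes were called, 980 higher and 862 lower.

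**Figure D3:**
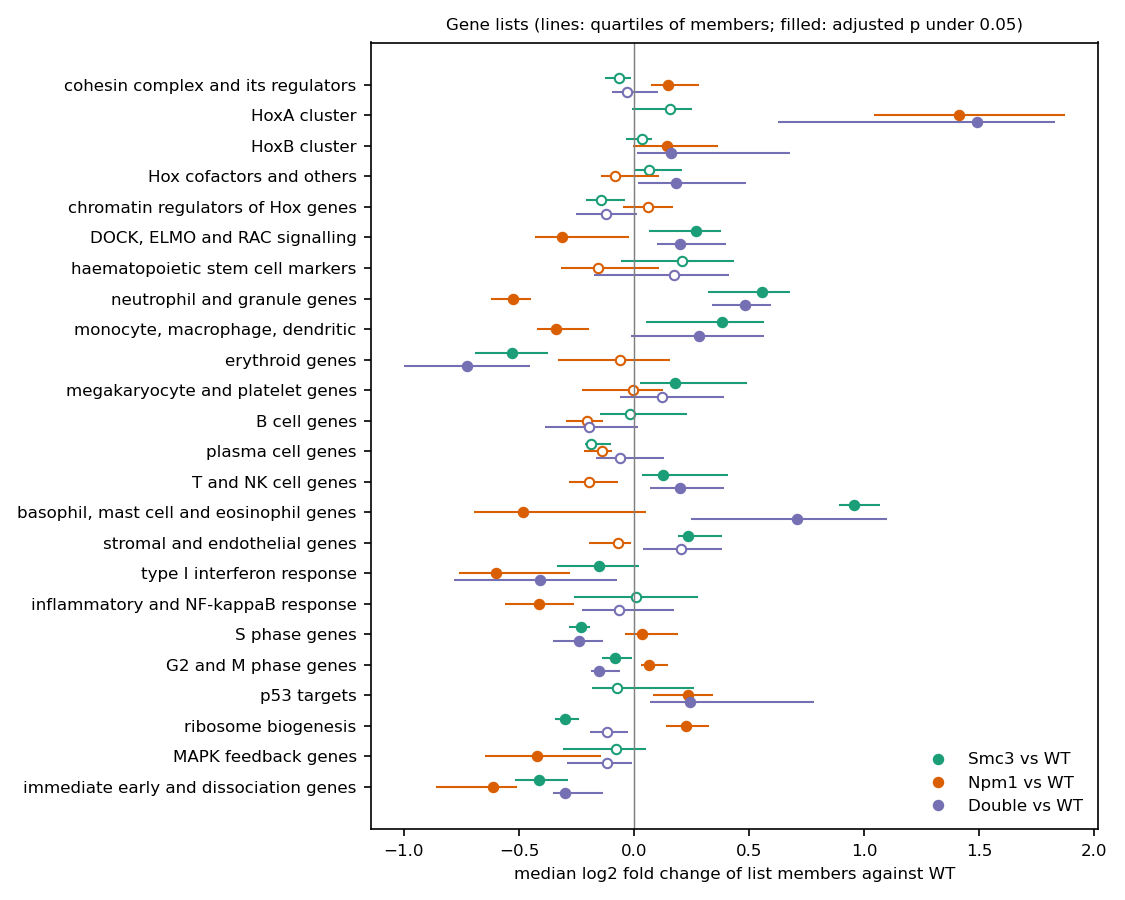
Median log2 fold change against WT (horizontal axis) of the members of 24 gene lists (vertical axis) in the 3 deposited comparisons. Lines span the quartiles of the members, filled points have a cameraPR adjusted p under 0.05, and the basophil, mast cell and eosinophil list lies at 0.96 in Smc3, -0.48 in Npm1 and 0.71 in Double.

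Genes called in Double were set against those called in each other genotype group. Among 12730 genes tested in both tables, 978 changed the same way in Smc3 and Double, 551 higher and 427 lower. Independent lists would share 91.6 and 85.5, and 1 gene changed the opposite way. Among 12312 genes, 475 changed the same way in Npm1 and Double, 190 higher and 285 lower against 105 and 116 for independent lists, and 95 changed opposite ways. In Smc3 and Npm1, 132 of 12291 genes changed the same way, 28 higher and 104 lower against 88.8 and 75.9 for independent lists, and 267 opposite ways. With the GC trend removed, the Smc3 and Double overlap in the same direction was 786, the Npm1 and Double overlap in the same direction 275 (79 higher and 196 lower) and the Smc3 and Npm1 overlap in the same direction 72 (9 higher and 63 lower). How many shared calls the WT libraries add among changed genes was not estimated. Across 11069 genes, which are not independent replicates, Pearson's r was 0.77 for Smc3 with Double, 0.23 for Npm1 with Double and -0.21 for Smc3 with Npm1. All 3 share the WT libraries, and unchanged groups simulated against shared WT libraries gave an r of 0.41, 0.41 and 0.42. The covariances were 0.0732, 0.0236 and -0.0190, beside 0.009, 0.00895 and 0.00891 simulated. With the GC trend removed r was 0.77, 0.11 and -0.30 and the covariance 0.0686, 0.01 and -0.024, so that of Npm1 with Double came close to the simulated value. The 3 WT libraries could not be split, and part of the excess may come from them.

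**Figure D4:**
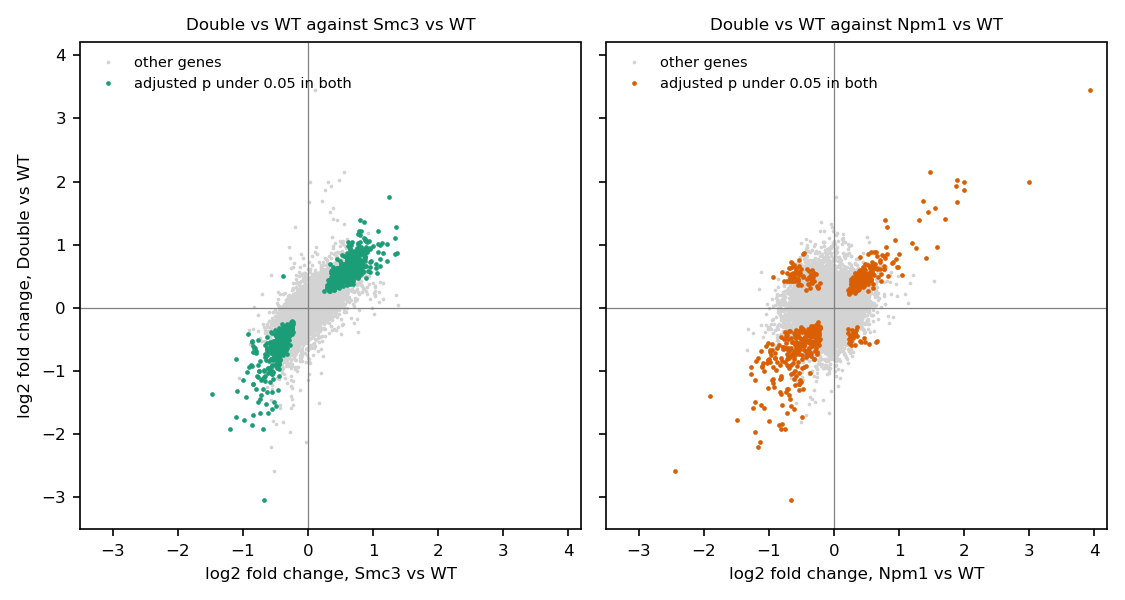
Log2 fold change of Double against WT (vertical axis) and of Smc3 or Npm1 against WT (horizontal axes) for genes with a mean of at least 50 normalized counts. Coloured points passed an adjusted p of 0.05 in both comparisons, and Pearson's r is 0.77 for Smc3 and 0.23 for Npm1.

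The comparison of Double with Npm1 asked what the Smc3 genotype added on Npm1, with male libraries in Double and none in Npm1, so that sex differs along with genotype. Dock1 was higher in Double than in Npm1 by 1.15 ± 0.29 on the log2 scale (z test of the difference, adjusted p = 0.0035), Rac2 by 0.77 ± 0.21 (adjusted p = 0.00712) and Elmo1 by 1.13 ± 0.23 (adjusted p = 0.00025), as computed from the authors' deposited table of each comparison. Elmo1, Cpa3, Elane and Klf1 were chosen after their values were seen. By the same z test from the authors' deposited tables, Cpa3 differed by 1.33 ± 0.25 (adjusted p = 4.14e-05) and Elane by 1.26 ± 0.29 (adjusted p = 0.00125), while the erythroid factor Klf1 differed by -0.79 ± 0.16 (adjusted p = 0.000186). The most positive differences from the authors' deposited tables were Serpina3f at 1.70 ± 0.34, Klrb1f at 1.56 ± 0.27, Sgms2 at 1.53 ± 0.27, the deiodinase Dio2 at 1.53 ± 0.21 and Ak4 at 1.45 ± 0.26. The most negative from the authors' deposited tables were Spon2 at -2.38 ± 0.30, the glypican Gpc4 at -1.58 ± 0.26, Prss50 at -1.30 ± 0.27, Tspan15 at -1.28 ± 0.31 and Ptpn13 at -1.26 ± 0.30. Hoxa9 differed by -0.01 ± 0.17 (95% interval -0.34 to 0.32) and Hoxa10 by -0.49 ± 0.28 (-1.03 to 0.05), neither past the threshold.

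In Double against Npm1, 1283 of 18379 genes passed, 752 higher and 531 lower. The z test ignores the shared WT variance and is strict in that respect, and 3138 passed with that share removed. It does not cover moderation that is unequal between the comparisons. Among the lists, 11 of 26 (13 adjusted over the list alone) DOCK, ELMO and RAC genes were higher (cameraPR adjusted p = 1.13e-10), as were 11 of 14 (13 adjusted over the list alone) basophil, mast cell and eosinophil genes (3.35e-14), 8 of 20 (9 adjusted over the list alone) neutrophil genes (2.76e-05, 4.85e-12 over the 10 with a p in both tables) and 7 of 28 (7 adjusted over the list alone) monocyte genes (4.89e-07). Erythroid genes were lower in 10 of 21 (19 adjusted over the list alone) (cameraPR adjusted p = 4.94e-16), S phase genes in 7 of 25 (10 adjusted over the list alone) (3.67e-10), G2 and M phase genes in 2 of 26 (2 adjusted over the list alone) (9.05e-06) and ribosome biogenesis genes in 1 of 25 (2 adjusted over the list alone) (2.57e-06). The T and NK cell list was also higher with 1 of 19 (2 adjusted over the list alone) called, Nkg7 among them (cameraPR adjusted p = 0.000464), and the cohesin list lower with 1 of 15 (1 adjusted over the list alone) called, Wapl (0.004). The immediate early, NF-kappaB, stromal, Hox cofactor and Hox chromatin regulator lists had cameraPR adjusted p = 0.0102, 0.0149, 0.0143, 0.0352 and 0.0378, and 0.0592, 0.0784, 0.0592, 0.0864 and 0.0989 at a correlation of 0.05. The first 4 were higher in Double (median differences 0.33, 0.36, 0.30 and 0.18) and the chromatin regulators lower (-0.25). Called over all genes were Egr1 (higher), Tnfaip2 (lower, against its list), Pdgfrb (higher), 0 cofactors and Mllt3 (lower). Adjusted over the list alone, 1 immediate early gene was higher, 2 NF-kappaB genes higher and 1 lower, 1 stromal gene higher, 0 cofactors and 3 chromatin regulators lower. The other 10 lists stayed called at that correlation, and at a mean of at least 50 the cohesin, Hox cofactor, Hox chromatin regulator and stromal lists were not called (0.0501, 0.0821, 0.189 and 0.13). With the GC trend removed the split was 940 higher and 388 lower, and with the median set to 0 it was 862 and 428. The lists of this difference were not tested with the GC trend removed. Against WT, that removal moved the cohesin median from 0.145 to -0.006 in Npm1 and from -0.031 to -0.083 in Double.

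The comparison of Double with Smc3 asked what the Npm1 genotype added on Smc3, with male libraries in both groups. HoxA genes and p53 targets were higher in Double, by 3.34 ± 0.32 for Hoxa10 (z test, adjusted p = 2.84e-21), 1.69 ± 0.20 for Hoxa9 (adjusted p = 5.95e-13), 1.57 ± 0.30 for Phlda3 (adjusted p = 0.000189) and 1.53 ± 0.34 for Eda2r (adjusted p = 0.00387), from the authors' deposited tables. Mgat4c at 1.98 ± 0.35, Hopx at 1.65 ± 0.32 and Hoxa5 at 1.61 ± 0.27 were the other genes among the 5 most positive, and Spon2 at -2.37 ± 0.30, Cd248 at -2.09 ± 0.35, Tinagl1 at -2.06 ± 0.31, the gastric proton pump gene Atp4a at -1.67 ± 0.33 and Slc26a1 at -1.64 ± 0.29 the most negative, from the authors' deposited tables. Dock1 differed by 0.17 ± 0.28 (95% interval -0.38 to 0.72) and Rac2 by -0.28 ± 0.20 (-0.67 to 0.11), neither past the threshold. Of 18779 genes 51 passed, 17 higher and 34 lower, and 185 passed with the shared WT variance removed. Of the HoxA genes 6 of 10 (7 adjusted over the list alone) were higher (cameraPR adjusted p = 2.73e-62), and of the p53 targets 2 of 23 (5 adjusted over the list alone) (5.97e-19). As lists, with 0 members called over all genes, HoxB (0.000101) and ribosome biogenesis genes (2.9e-06) were higher in Double, and interferon (5.37e-12), basophil (0.000687), B cell (0.00104) and erythroid genes (0.00256) lower by cameraPR adjusted p. All 8 lists stayed called at a correlation of 0.05, and on ranks the basophil, mast cell and eosinophil list did not (adjusted p = 0.212). Phlda3 and Eda2r carry no p in Smc3 against WT, and the p53 list without them had cameraPR adjusted p = 4.04e-12. Adjusted over the list alone, 1 HoxB, 0 ribosome biogenesis, 2 interferon, 2 basophil, 0 B cell and 0 erythroid genes passed in those directions.

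The last comparison asked whether Double departed from the sum of the Smc3 and Npm1 log2 changes. No gene did by the z test with Benjamini-Hochberg adjustment (0 of 18199, 265 at an unadjusted p under 0.05, smallest adjusted p = 0.113), a test that ignores the shared WT variance and is strict in that respect. On simulated data it recovered 71.7% of departures of 1 and 99.4% of departures of 2 on the log2 scale. Those departures were set in genes with a mean of at least 50 and were not moderated towards 0, so real recovery may be lower. With the shared WT variance removed 4 genes passed, named here after their values were seen. They were Spon2 at -1.71 ± 0.32 (adjusted p = 0.00235) and AA465934 at -1.52 ± 0.31 (adjusted p = 0.0092), below the sum, and Serpina3f at 1.66 ± 0.35 (adjusted p = 0.00926) and Egr1 at 1.51 ± 0.34 (adjusted p = 0.0414), above it, from the authors' deposited tables. Egr1 stood at -0.66, -1.25 and -0.40 in Smc3, Npm1 and Double. Moderation towards 0 can be unequal between the comparisons, and its part in the departures of genes and lists was not tested. Dock1 lay 0.80 ± 0.35 above the sum (95% interval 0.11 to 1.49, adjusted p = 1.00) and Rac2 0.40 ± 0.25 (-0.09 to 0.88, adjusted p = 1.00), neither past the threshold. As lists, 14 departed from the sum with 0 members called over all genes. Adjusted over the list alone, 7 immediate early genes passed and 0 members of the other 13. Immediate early genes lay above it by a median of 0.77 (cameraPR adjusted p = 5.28e-23), as did MAPK feedback (0.50, 4.25e-05), NF-kappaB (0.37, 8.02e-06), neutrophil (0.30, 1.05e-06), DOCK, ELMO and RAC (0.23, 7.71e-07), interferon (0.22, 0.000118), monocyte (0.20, 0.00391), T and NK cell (0.27, 0.00582) and plasma cell genes (0.23, 0.0267). Below it lay G2 and M phase (-0.14, 3.21e-05), cohesin (-0.14, 0.00567), HoxA (-0.26, 0.00928), S phase (-0.08, 0.0105) and erythroid genes (-0.27, 0.0102). At a correlation of 0.05 the plasma cell, S phase and erythroid lists were not called (adjusted p = 0.0582, 0.0659 and 0.0582). At a mean of at least 50, where fewer genes are tested, 8 of the 14 stayed called, and the cohesin, HoxA, T and NK cell, plasma cell, S phase and erythroid lists did not (adjusted p = 0.0512, 0.0562, 0.0645, 0.0553, 0.0737 and 0.0733). Over the 10 neutrophil genes with a p in every table the adjusted p was 4.13e-06. WT enters the departure with the sign of Double, so a chance value of the WT libraries moves every departure.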

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

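The depth test below was written before its result was seen and the others after. Genes of the Y chromosome stood out because the labels give no sex and the main test called the sex-linked list, which holds them, in no comparison. The summed mean of Ddx3y, Uty, Kdm5d and Eif2s3y was 2021.84 normalized counts in the Smc3 and WT libraries and 2280.47 in the Double and WT libraries, against 3.80 in the Npm1 and WT libraries. Xist, the RNA of the silenced X, lay at 33.5% of its WT level in Smc3 and 40.7% in Double, where 33.3% is the value if 1 of 3 libraries expresses it. Male libraries thus sit in Smc3 and Double and not in WT or Npm1.

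Smc3 and Double moved together across genes, with a covariance of 0.0732. By the standard errors, random variation of the shared WT libraries can add at most 0.0180, which argues against that variation as the whole cause. A shift common to all WT libraries is not in the standard errors and is not bounded by this value. Depth was argued against by genes with a mean of at least 1000, where Double minus Npm1 and Smc3 against WT, which share no library, had r = 0.830 over 5039 genes. The male libraries cannot be told apart from the genotype, as Xist at 33.5% and 40.7% of WT marks both groups, and a shared batch would act in the same way. An effect of the Smc3 genotype also stays open, untested.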

How the results depend on the processing

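No paired analysis was possible because the tables hold no values per library, and the replicate block, leaving out each library, edgeR or DESeq2 on counts, other normalizations, a pseudocount, other splits of the samples and an estimated correlation were not run for the same reason. GC removal, the 2 other transcript choices and leaving out genes without a p were chosen after seeing the data. Removing the WT share of the variance, by construction a smaller variance, raised the calls to 3138 for Double against Npm1, 185 for Double against Smc3 and 4 for Double against the sum. Smc3 vs WT genes changed, Npm1 vs WT genes changed and Double vs WT genes changed were 793, 932 and 1410 at adjusted p under 0.01, 49, 74 and 156 at a log2 change of at least 1, 557, 672 and 1118 by Benjamini-Yekutieli and 150, 206 and 422 by Bonferroni adjustment, all stricter by construction, and Smc3 had 2832 at 0.1. The Smc3 and Double overlap in the same direction, the Npm1 and Double overlap in the same direction and the Smc3 and Npm1 overlap in the same direction were 384, 217 and 42 at 0.01, 1552, 720 and 245 at 0.1, and 16, 33 and 1 at a log2 change of at least 1. With the GC trend removed, Npm1 vs WT genes changed were 1385, the overlaps with Double and Smc3 were 275 and 72, and the Npm1 vs WT list: sex-linked genes changed direction (adjusted p = 0.0165). That list had a median GC content of 40.5% and a median log2 fold change of 0.03, which the subtraction moved to -0.17. Its Y-linked genes lie near the floor there, with a summed mean of 3.80, so the new direction comes from the subtraction. Why the counts fell was not tested. For Double vs sum of single genotypes, gene lists called were 8 at a mean of at least 50, where fewer genes are tested. Without genes that lack a p, Double vs Npm1 genes changed were 1282, Double vs Smc3 genes changed 49 and Double vs sum of single genotypes genes changed 0, with 15, 8 and 14 lists called. Of 75 list results against WT, 66 kept their side of the threshold under GC removal, 65 at a correlation of 0.05, 66 at a mean of at least 50 and 67 on ranks, and 62, 65, 63 and 65 of these kept their direction too. Of 75 list results for differences, 8 lost their call at a correlation of 0.05 and 10 at a mean of at least 50, and on ranks 2 lost and 4 gained it. Removal of the GC trend was not run for these 75 results. Of 702 named gene results 643 kept their side under GC removal, 600 with their direction, and of 708 results 684 did with adjustment over all transcripts, 684 with their direction, and 688 with the median set to 0, 676 with their direction. At this depth and with 3 libraries a group, changes of 0.5 on the log2 scale were recovered in 23.1% of simulated cases for Double against Npm1. Those changes were unmoderated and set in genes with a mean of at least 50.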

Other observations

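The tests in this part, and the genes of its first 2 paragraphs, were chosen after the results were seen. Some named genes went opposite ways in Smc3 and Npm1. In the Smc3, Npm1 and Double comparisons, in that order, Alox15 stood at 1.38, -0.90 and 0.04 in the authors' deposited table, Cd200r3 stood at 1.36, -0.80 and 0.21, and Fcer1a stood at 0.98, -0.69 and -0.01, each past the threshold in Smc3 and Npm1 and not in Double. Cpa3 (1.33, -0.48, 0.85) and Ms4a3 (0.75, -0.80, 0.57) and Cd34 (0.62, -0.69, 0.43) passed in all 3 and followed Smc3 in Double, in the authors' deposited table. Elmo1 (0.57, -0.51, 0.62) and Arhgdib (0.55, -0.56, 0.46) did the same, while Rac2 (0.38, -0.68, 0.10) did not pass in Double, in the authors' deposited table. Of the 267 genes that changed opposite ways, 186 were higher in Smc3 and lower in Npm1, against 88.4 for independent lists.

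The ribosome biogenesis gene Ddx21 and the S phase gene Ccne1 went the other way, among 81 genes lower in Smc3 and higher in Npm1 (76.2 for independent lists). Of the genes higher in Double, 523 were also higher in Smc3 only, 162 in Npm1 only, 28 in both and 459 in neither. Of the genes lower in Double, 343, 201, 84 and 670 fell in those classes. A gene in neither missed the threshold in that direction in Smc3 and in Npm1, and is not thereby particular to Double. By the z test 1283 genes differed between Double and Npm1, 51 between Double and Smc3, and 0 departed from the sum. Double and Smc3 both hold male libraries, with mean size factors of 2.1 and 2.15 times WT. Npm1 holds none, at 1.36 times WT, so the first 2 counts do not rest on genotype alone. Double minus Npm1 followed Smc3 against WT with r = 0.81 across 11069 genes, and Double minus Smc3 followed Npm1 against WT with r = 0.64. With the GC trend removed r was 0.82 and 0.59. Male libraries sit in Double and Smc3 and not in Npm1 or WT, so both sides of the first relation carry the same sex contrast. The slopes, over genes called in Smc3 against WT and in Npm1 against WT, were 1.09 and 0.479.

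Immediate early genes, which respond to stress and tissue handling, were lower as a list in each genotype group. Uneven recovery of fragments by GC content was argued against in Smc3 (adjusted p = 1.88e-05 with the trend removed) and Npm1 (4.92e-08). In Double removal ended the call (adjusted p = 0.131), as did a correlation of 0.05 (0.0877) and a mean of at least 50 (0.155), with 0 of 20 members called. The median in Double moved from -0.30 to -0.19 with the trend removed, and ranks kept the call (cameraPR adjusted p = 0.00054). WT libraries handled differently from the rest also stay open, since the list differed between Double and Npm1 at the preset correlation (cameraPR adjusted p = 0.0102) but not at 0.05 (0.0592). On ranks and at a mean of at least 50 this difference stayed called (cameraPR adjusted p = 0.00153 and 0.0165). A genotype effect also stays open, untested.

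In Smc3 and Double erythroid genes were lower and members of the basophil, mast cell and eosinophil list higher, with 11 of 11 tested members called in Smc3 and 8 of 14 in Double. A smaller share of erythroid cells would raise all other types alike, yet the median of that list exceeded the B cell median by 0.98 in Smc3 (permutation p = 1.6e-04, 11 and 18 genes) and 0.90 in Double (permutation p = 4e-05, 14 and 17 genes). Only the B cell list was compared. Medians of the monocyte, stromal, megakaryocyte and T and NK cell lists were 0.38, 0.23, 0.18 and 0.13 in Smc3. In Double they were 0.28, 0.20, 0.12 and 0.20. The plasma cell median was -0.19 in Smc3 and -0.06 in Double. The test bears on an equal rise alone, so a smaller erythroid share as part of the pattern stays open. GC content was argued against, as the largest adjusted p of these lists with the trend removed was 3.28e-07. Permuted genes are not independent, and male libraries sit in the same groups. Red cell lysis and lineage depletion, which take away erythroid and B cells, stay open if they were uneven between groups, as does the Smc3 genotype, both untested.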
